A study of Drosophila melanogaster with 12 samples.

How the data were processed

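RNA was measured by sequencing in wing imaginal discs of Drosophila melanogaster w1118 larvae. Per the labels, the discs were dissected 24 h after the moult from the second to the third larval instar and cultured for 2.5 h at 25°C. The medium held 0, 20, 200 or 2000 nM 20-hydroxyecdysone (20E), the active form of the insect moulting hormone. Each dose had 3 libraries, 12 in all. Per the labels, RNA was extracted with RNeasy and libraries were made with the NEBNext Ultra II Directional kit and poly(A) selection, although the labels also give total RNA as the molecule. They do not say whether replicates were separate cultures or animals, so the p-values measure only the spread between these libraries. Per the submitters' processing notes, HISAT2 2.1.0, SAMtools 1.13, Subread 2.0.1 and DESeq2 1.32.0 were used, with no settings named. The genome build, the annotation and the strand setting of the read counting are not given in the sources used here, so no coordinates are given.

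The deposited table holds 12216 genes with 1 value per library, in a unit read here as signal: counts the authors divided by a size factor per library, per the file headers and a test of the values. A factor for each library turned 100% of its values into whole numbers within 0.001, and the reads per library below are the sums of those numbers. The table also gives each gene's mean over the 12 libraries, a log2 fold change of 2000 nM against 0 nM with its standard error, a test score, and a p-value with an adjusted p-value, all computed by the authors. The deposited p-value was that of a chi-square with 3 degrees of freedom for the deposited score, which is the distribution of a likelihood ratio test over the 4 doses. The adjusted p-value is missing for 2842 genes. Gene symbols are those of the deposited table, and 1155 entries without one are named by their identifier. An annotation of the BDGP6.54 assembly (Ensembl 115) served only to look up current symbols, gene families and overlapping exons, and 12167 of the 12216 identifiers were found in it.

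Libraries held 9034719 to 27006374 reads, 2.99 times as many in the deepest as in the shallowest. A single read equalled 0.565 to 1.69 normalised counts across the 12 libraries. Genes were tested if their normalised count was at least 10 in at least 3 of the 12 libraries, which kept 8455. The values were log2 transformed after adding 1 and fitted with limma 3.58.1 in R 4.3.3. The model had 1 mean per dose, no block and 8 residual degrees of freedom, and the empirical Bayes step used an intensity trend. The 6 pairwise comparisons used limma's two-sided moderated test, and a moderated F test over the 3 contrasts with 0 nM tested for a difference at any dose. P-values were adjusted by Benjamini-Hochberg over the 8455 genes, with a threshold of 0.05. Genes were called dose-reversing when both 20 nM against 0 nM and 2000 nM against 20 nM passed the threshold with opposite signs. In the text, "rose", "fell" and "changed" are used only for genes past that threshold. Levels are mean normalised counts ± SD with n = 3 libraries. Log2 fold changes are differences of mean log2 values ± SE, with 3 libraries per dose, and folds are their antilogs. Folds from a base of few counts therefore depend on the added 1. For a gene with 1 to 3 reads in a whole dose group, the ratio of reads per normalised count is given instead, with a 95% interval (exact, Clopper-Pearson) that covers counting error only.

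Before the data were examined, 22 gene lists with 405 members were fixed, 383 of them in the table. They were ecdysone response genes, ecdysteroid synthesis and import genes, DNA replication and G1/S genes, G2/M and mitosis genes, ribosome biogenesis genes, wing patterning and growth signalling genes, Hippo pathway and Yorkie target genes, insulin, TOR and FOXO genes, Notch target genes, apoptosis and wound stress genes, heat shock genes, oxidative stress and detoxification genes, glycolysis genes, cell shape and disc eversion genes, cuticle and apical matrix genes, and markers of fat body, blood cells, adult muscle precursors, trachea, neurons and glia, salivary gland and other imaginal discs. Lists were tested per comparison with camera from limma at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with an estimated correlation. The salivary gland list had fewer than 3 tested members and was left out of the list tests. The named genes followed a rule fixed at the same time. It took, per comparison, up to 10 higher and 10 lower genes by absolute log2 fold change, among genes past the threshold. They needed a mean of at least 50 in the higher group and replicates that do not overlap between the groups, which chance gives in 10% of genes at 3 against 3. Symbols that are only a CG or CR number, a long non-coding RNA code or an antisense RNA were left out. The rule added up to 4 members per list with the smallest adjusted p, up to 10 dose-reversing genes per direction, and EcR, usp, br, Eip74EF, Eip75B, Eip78C, Hr3, Hr4, ftz-f1, stg, CycE and Myc, each at least once. Of these Hr3, at most 8.94 normalised counts in any library, did not pass the filter and was not tested. Of the 205 genes so named, 27 share exon sequence with another gene, and in 12 of these the other gene's level is over 50% of the named gene's.

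The alternatives were pseudocounts of 0.5 and 5, no filter, a filter at 50, scaling by a trimmed mean of M values (TMM, trimming 30% and 5%), quantile normalisation, the replicate number as a block, a fit of only the 2 doses compared, and a minimum change of 2-fold. Each of the 12 libraries was also left out in turn. Chosen after seeing the data were limma-voom on the recovered reads, all libraries thinned to the reads of the shallowest, and the authors' likelihood ratio test. The scripts were first tested on simulated data with 200 of 8455 genes changed, drawn from those with a mean of at least 50 normalised counts. Recovery at lower means was not simulated. In the simulated 2000 nM against 200 nM comparison the fit recovered 82.1% of 1.5-fold and 100% of 2-fold changes. The simulated genes varied independently, and no change under 1.5-fold was simulated. With 200 changed genes the adjusted threshold is looser than with the 17 genes called in the real comparison. These rates therefore do not carry over to it. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.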

Results

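The series measured RNA in cultured Drosophila wing imaginal discs, the larval epithelia that form the adult wings, after 2.5 h with 0, 20, 200 or 2000 nM 20E, with 3 libraries per dose. Its title asks how the effects of the hormone depend on its level. The 0 nM libraries held 11490448, 14369671 and 24596727 reads, and the 20 nM libraries 9034719, 27006374 and 22613301. The 200 nM libraries held 9910007, 10097976 and 15364096 reads, and the 2000 nM libraries 25865047, 9908492 and 20682453. The 10 most abundant genes took 5.94% to 7.11% of a library's reads. Replicates of a dose correlated at 0.984 to 0.994 across genes on the log2 scale, where genes are not independent replicates. The first principal component, with 53.7% of the variance, ordered the libraries by dose. The second, with 11.3%, spread the replicates within each dose, from -17.6 to 13.3 at 20 nM and from -13.8 to 24.3 at 2000 nM. The median SE of a log2 fold change was 0.109. The number of genes past the threshold grew from 381 at 20 nM to 2618 at 2000 nM, each against 0 nM, while 17 genes differed between 2000 and 200 nM.

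**Figure D1:**
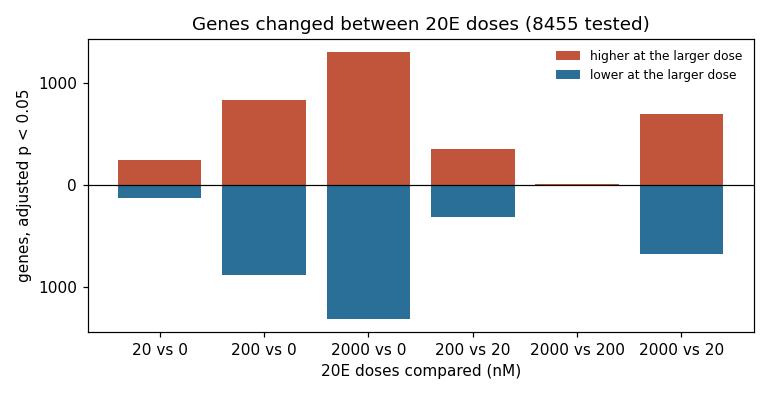
Bars give the number of genes higher (up) or lower (down) in each of the 6 comparisons, of 8455 tested, at an adjusted p under 0.05. The bars for 2000 nM against 200 nM hold 14 higher and 3 lower genes.

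The 20 nM dose asks what the discs do at a low hormone level, and 251 genes rose and 130 fell against 0 nM. Without 20 nM replicate 2 these numbered 190 and 79. Eip75B (FBgn0000568), a nuclear receptor gene induced early by ecdysone, rose 46.2-fold, from 104 ± 11.9 to 4860 ± 397 normalised counts (SD, n = 3). The bZIP transcription factor gene vri rose 28.3-fold and Cyp18a1 (FBgn0010383), which encodes an enzyme that inactivates 20E, rose 17.5-fold. ImpE1 and ImpE2, genes known for their induction by ecdysone in imaginal discs, rose 11.9-fold and 13.0-fold. The nuclear receptor gene Eip78C rose 8.39-fold, bip1 6.76-fold and the cuticle protein gene Cpr49Ac 6.22-fold. Broad (br, FBgn0283451), a zinc-finger transcription factor gene, rose 4.39-fold, Eip74EF (FBgn0000567), an ETS factor gene, 4.21-fold, and the nuclear receptor gene Hr4 (FBgn0264562) 2.77-fold.

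Genes that fell at 20 nM included chinmo, a BTB transcription factor gene, by 4.17-fold, hdc by 3.72-fold, Obp83g by 4.39-fold, Picot by 3.33-fold and Ugt35A1 by 2.74-fold. EcR (FBgn0000546), which encodes the ecdysone receptor, fell from 5319 ± 228 to 2780 ± 116 normalised counts, a log2 fold change of -0.94 ± 0.09 (SE). Its partner usp, whose exons overlap those of Actn on the same strand, stood at 1457 and 1449 normalised counts and was not called. The nuclear receptor gene ftz-f1 (FBgn0001078) fell by 3.09-fold (adjusted p = 0.0216, range 1.16e-06 to 0.0878 over its alternatives). That call ended without 0 nM replicate 1 (0.0682), replicate 2 (0.0623) or replicate 3 (0.0664), and without 20 nM replicate 1 (0.0783) or replicate 2 (0.0878).

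By list, 12 of the 22 tested ecdysone response genes rose and 2 fell at 20 nM, or 14 and 2 adjusted over the list alone. The list was called at adjusted p = 8.57e-22, and at adjusted p = 0.00454 with an estimated correlation. Of 32 wing patterning and growth signalling genes, 6 rose and 1 fell (13 and 1 adjusted over the list alone), among them the Wnt gene Wnt6 by 0.52 ± 0.07 log2, and the transcription factor genes Dll by 0.51 ± 0.08 and nub by 0.35 ± 0.06. The list passed at adjusted p = 9.4e-07, but had adjusted p = 0.309 with an estimated correlation, and 4 of its genes rose and none fell without 20 nM replicate 2. The growth regulator Myc rose by 0.81 ± 0.12 log2 and was one of 4 of 28 ribosome biogenesis genes that rose, 4 also adjusted over the list alone, with none falling (adjusted p = 5.24e-06, and adjusted p = 0.293 with an estimated correlation). Without 20 nM replicate 2 the count was 2, and without 0 nM replicate 3 it was 1, Myc. The phosphatase gene stg (FBgn0003525), which drives entry into mitosis, fell by 0.52 ± 0.10 log2 (adjusted p = 0.00681). It was the only member of the 42 G2/M and mitosis genes past the threshold, also adjusted over the list alone, and the list lay lower at adjusted p = 3.19e-06, but had adjusted p = 0.393 with an estimated correlation. Without 20 nM replicate 1, 2 of its genes fell.

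Pdk1, a kinase gene of the insulin pathway, rose by 2.26 ± 0.09 log2 at 20 nM and the insulin receptor gene InR by 1.00 ± 0.15. They were the 2 of 15 insulin, TOR and FOXO genes that rose, with 1 falling (4 and 1 adjusted over the list alone). The list had adjusted p = 0.0363, range 0.0116 to 0.0818 over its alternatives, and adjusted p = 0.293 with an estimated correlation. It was lost without 20 nM replicate 1 (0.0529), without 0 nM replicate 3 (0.0618) and with limma-voom (0.0818), and 4 of its genes rose and 1 fell without 200 nM replicate 2. Of 13 glycolysis genes, 3 fell and none rose (4 and 1 adjusted over the list alone, adjusted p = 0.00228, and adjusted p = 0.393 with an estimated correlation). Their count was 1 without 0 nM replicate 1 or 20 nM replicate 1, and 0 without 20 nM replicate 2 or 0 nM replicate 3. The DNA replication and G1/S list lay lower at adjusted p = 0.00896, range 0.000332 to 0.279 over its alternatives, and at adjusted p = 0.724 with an estimated correlation. Its only called gene of 34, E2f1, an S-phase transcription factor gene, rose by 0.42 ± 0.07 log2, also adjusted over the list alone. That list was lost without 0 nM replicate 3 (0.279) and without 20 nM replicate 3 (0.0962).

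At 200 nM, 839 genes rose and 882 fell against 0 nM. Cyp18a1 rose 211-fold, ImpE1 210-fold, Hr4 187-fold, Eip78C 163-fold and ImpE2 128-fold. The 0 nM libraries held 9, 17 and 10 reads of Cyp18a1. In them Hr4 stood at 22.25 to 25.29 normalised counts and Eip78C at 10.47 to 15.98. Folds from such low levels depend on the 1 added before the log2 step. The gene of the transcription factor Blimp-1 had 1 read in all 0 nM libraries together and reached 2678 ± 242 normalised counts at 200 nM, a ratio of 8763 with a 95% interval of 1572 to 346200. Eip75B rose 72.8-fold, the extracellular matrix gene tnc 51.9-fold, phm, which encodes an enzyme of ecdysone synthesis, 41.7-fold, and br 8.93-fold. The fold of phm also starts from few reads, 7, 4 and 14 in the 0 nM libraries. Falls included those of ftz-f1, by 37.1-fold from 2203 ± 40.2 to 59.8 ± 14.9 normalised counts, hdc by 26.7-fold, chinmo by 23.1-fold, Obp83g by 19.1-fold, DOR by 11.5-fold and the transcription factor gene fru by 10.9-fold. EcR fell by 1.58 ± 0.09 log2.

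By list at 200 nM, 14 of 22 ecdysone response genes rose and 4 fell, also adjusted over the list alone, with adjusted p = 6.51e-11 and adjusted p = 0.0433 with an estimated correlation. Of 42 G2/M and mitosis genes, 25 fell and none rose (27 and 1 adjusted over the list alone), with stg at -0.93 ± 0.10 log2 and the cytokinesis genes tum at -0.59 ± 0.07 and feo at -0.45 ± 0.07. The list was called at adjusted p = 1.7e-08, but had adjusted p = 0.331 with an estimated correlation. Of 13 glycolysis genes, 10 fell and 1 rose, also adjusted over the list alone (adjusted p = 6.77e-07, and adjusted p = 0.198 with an estimated correlation), including Pfk by 1.25 ± 0.09 log2, PyK by 0.90 ± 0.08 and Pgi by 0.84 ± 0.09. Among the wing patterning and growth signalling genes 18 rose and 1 fell (19 and 1 adjusted over the list alone, adjusted p = 6.77e-07, and adjusted p = 0.331 with an estimated correlation), with the Wnt gene wg up by 0.91 ± 0.08 log2 and rho, an activator of EGF receptor ligands, by 2.31 ± 0.19. The insulin, TOR and FOXO list held 5 rises and 1 fall (6 and 2 adjusted over the list alone, adjusted p = 0.00769, and adjusted p = 0.198 with an estimated correlation). They included Pdk1 at 3.76 ± 0.09 log2, ImpL2, which encodes a secreted insulin-binding protein, at 3.22 ± 0.33, and the lipase gene bmm at 2.60 ± 0.30.

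Of 19 apoptosis and wound stress genes, 8 rose and 1 fell at 200 nM (10 and 2 adjusted over the list alone, adjusted p = 0.0129, and adjusted p = 0.477 with an estimated correlation). The caspase gene Dronc rose by 1.33 ± 0.08 log2, and the cell death genes rpr and hid by 0.99 ± 0.13 and 0.95 ± 0.10. Of 28 ribosome biogenesis genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), with Myc up by 0.70 ± 0.12 log2. That list had adjusted p = 0.0166, range 0.00431 to 0.0688 over its alternatives, was lost without 0 nM replicate 1 (0.0688) and had adjusted p = 0.559 with an estimated correlation. Its rises numbered 5 without 0 nM replicate 1, 0 nM replicate 3 or 200 nM replicate 3. Of 7 genes listed as markers of other imaginal discs 5 rose and 1 fell, also adjusted over the list alone. Its members eyg and eya were up by 0.76 ± 0.07 and 0.81 ± 0.10 log2, and whether they mark other discs was not tested. That list had adjusted p = 0.0286, range 0.0116 to 0.0856 over its alternatives, was lost without 200 nM replicate 1 (0.0856), where 3 members rose, and had adjusted p = 0.438 with an estimated correlation. The DNA replication and G1/S list was not called (adjusted p = 0.0609), with 2 rises and 3 falls, also adjusted over the list alone. It held 2 rises and 1 fall without 200 nM replicate 1, 0 nM replicate 3 or 200 nM replicate 3, and 1 rise and 2 falls without 200 nM replicate 2. Its member CycE, the G1/S cyclin gene, rose by 0.48 ± 0.12 log2 (adjusted p = 0.0123, range 0.000971 to 0.056 over its alternatives), which was lost without 200 nM replicate 2 (0.056), and was not called in the other comparisons.

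At 2000 nM, 1306 genes rose and 1312 fell against 0 nM. Cyp18a1 rose 501-fold to 6104 ± 593 normalised counts, Hr4 469-fold to 11390 ± 848, ImpE1 329-fold, Eip78C 252-fold and ImpE2 173-fold. The folds of Cyp18a1, Hr4, Eip78C and phm start from the low 0 nM levels given above. Blimp-1 reached 4680 ± 713 normalised counts, a ratio to the single 0 nM read of 15810 with a 95% interval of 2838 to 624700. Eip75B rose 93.9-fold, tnc 83.8-fold, Cpr49Ac 45.4-fold and phm 43.1-fold. Falls included those of ftz-f1, by 83.5-fold to 31.7 ± 27.2 normalised counts, hdc by 32.3-fold, chinmo by 23.4-fold, Ugt35A1 by 15.7-fold, Picot by 14.2-fold and DOR by 13.3-fold. The ftz-f1 log2 fold change was -6.38 ± 0.38, and -7.02 without 2000 nM replicate 3. EcR fell from 5319 ± 228 to 1527 ± 192 normalised counts.

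**Figure D2:**
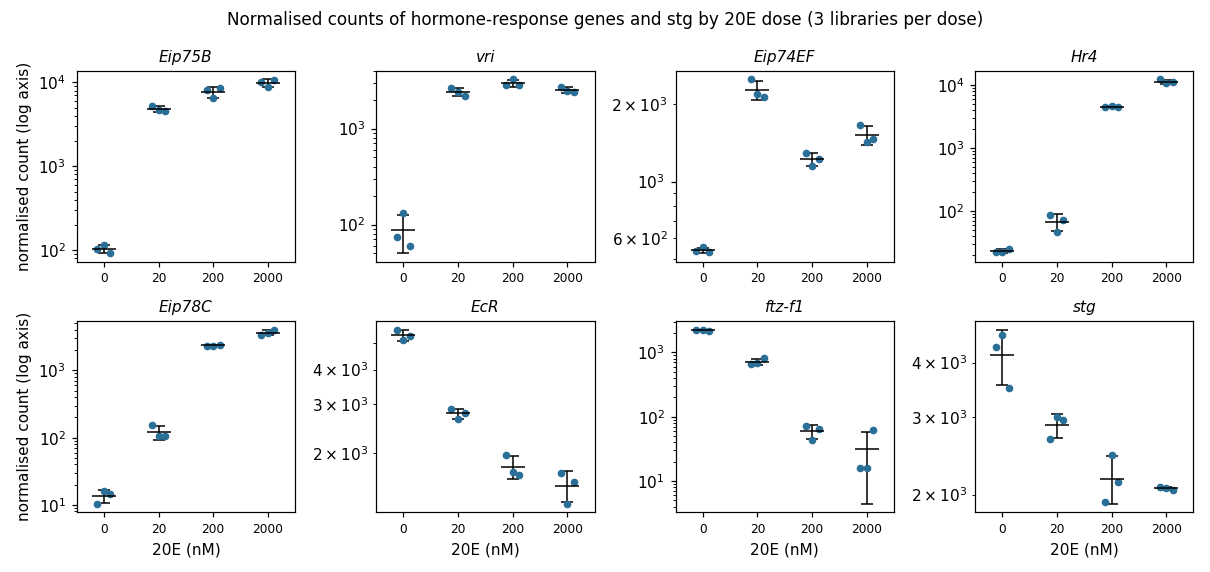
Points are single libraries, on a log axis of normalised counts against 20E dose in nM, and bars are means ± SD of 3 libraries for Eip75B, vri, Eip74EF, Hr4, Eip78C, EcR, ftz-f1 and stg. Eip75B stood at 4860 normalised counts at 20 nM and 9885 at 2000 nM, while Hr4 stood at 68.5 and 11390.

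By list at 2000 nM, 31 of 42 G2/M and mitosis genes fell and 1 rose (32 and 1 adjusted over the list alone, adjusted p = 6.64e-11, and adjusted p = 0.244 with an estimated correlation). The list's median was -0.45 log2, with stg down from 4156 ± 592 to 2068 ± 18.4 normalised counts, ncd at -0.78 ± 0.08 and tum at -0.77 ± 0.07. Of 34 DNA replication and G1/S genes 19 fell and 1 rose (24 and 1 adjusted over the list alone, adjusted p = 8.69e-06, and adjusted p = 0.504 with an estimated correlation), or 11 and 1 without 0 nM replicate 3 and 11 and 2 without 2000 nM replicate 3. The MCM helicase genes dpa and Mcm3 fell by 0.44 ± 0.07 and 0.53 ± 0.09 log2, as did dap, which encodes a Cdk inhibitor that restrains entry into S phase, by 0.71 ± 0.08, while E2f1 rose by 0.75 ± 0.07. Of 13 glycolysis genes 11 fell and 1 rose, also adjusted over the list alone (adjusted p = 5.67e-06, and adjusted p = 0.244 with an estimated correlation). Pfk fell by 1.37 ± 0.09 log2 and PyK by 1.14 ± 0.08, and the rising member was Ldh, the lactate dehydrogenase gene, at 3.31 ± 0.30.

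Ecdysone response genes at 2000 nM held 14 rises and 3 falls (14 and 4 adjusted over the list alone), with a median of 2.60 log2. That list was called at adjusted p = 1.18e-09, but had adjusted p = 0.0682 with an estimated correlation. Of 32 wing patterning and growth signalling genes 20 rose and 2 fell (21 and 2 adjusted over the list alone, adjusted p = 6.78e-08, and adjusted p = 0.244 with an estimated correlation), with wg at 1.22 ± 0.08 log2 and Wnt6 at 1.10 ± 0.07. Of 19 apoptosis and wound stress genes 12 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.000735, and adjusted p = 0.29 with an estimated correlation). Dronc rose by 1.64 ± 0.08 log2, rpr by 1.23 ± 0.13, hid by 1.08 ± 0.10 and kay, a Fos gene, by 0.57 ± 0.08. The insulin, TOR and FOXO list held 7 rises and 2 falls (8 and 2 adjusted over the list alone, adjusted p = 0.00564, and adjusted p = 0.244 with an estimated correlation), with Pdk1 at 4.06 ± 0.09 log2 and InR at 2.02 ± 0.15. Ribosome biogenesis genes were not called as a list at this dose (adjusted p = 0.645), with 5 rises and 2 falls, also adjusted over the list alone, or 3 and 2 without 2000 nM replicate 2 and 3 and 1 without 0 nM replicate 3.

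**Figure D3:**
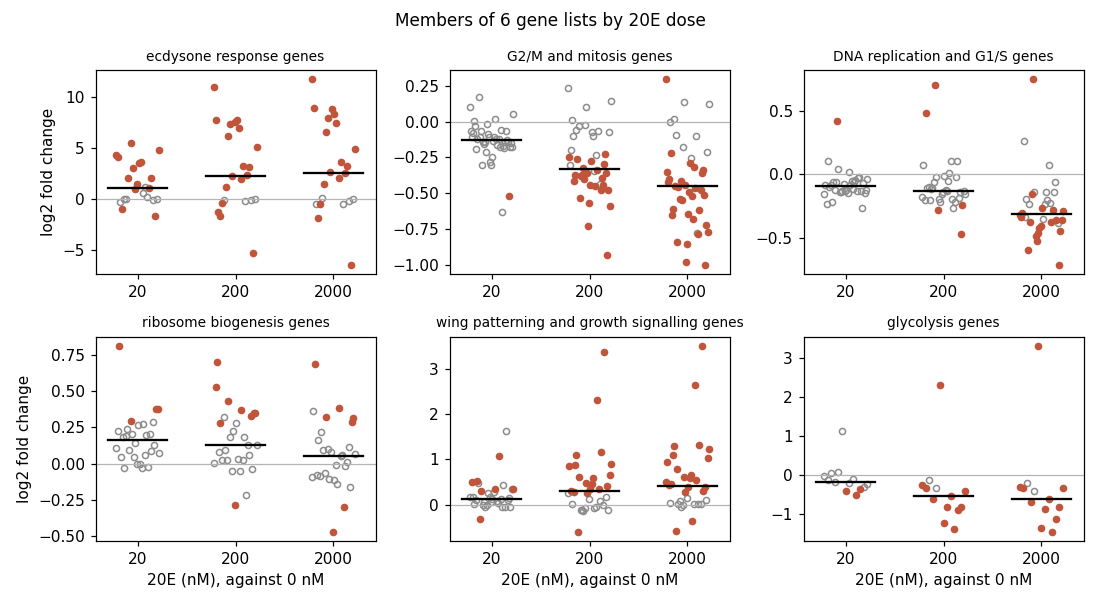
Points are the log2 fold changes against 0 nM of the members of 6 gene lists at 20, 200 and 2000 nM, filled where the adjusted p is under 0.05, and lines are list medians. At 2000 nM the median was 2.60 for ecdysone response genes, -0.45 for G2/M and mitosis genes and -0.61 for glycolysis genes.

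The remaining lists were not called at 2000 nM against 0 nM, though single members changed. The phm gene rose while Oatp74D, which encodes an importer of ecdysteroids, fell by 1.01 ± 0.07 log2, and the ecdysteroid synthesis and import list of 4 held 2 rises and 1 fall, also adjusted over the list alone (adjusted p = 0.655). Hippo pathway and Yorkie target genes held 5 rises, among them fj and wts, and 2 falls of 15, also adjusted over the list alone (adjusted p = 0.353), or 3 and 2 without 0 nM replicate 1 or 2000 nM replicate 2. Notch target genes held 3 rises, with nvy at 0.96 ± 0.10 log2, and 5 falls of 14, with E(spl)m7-HLH at -1.09 ± 0.14, also adjusted over the list alone (adjusted p = 0.645). Heat shock genes held 5 rises, with Hsp27 at 2.07 ± 0.15 log2, and 2 falls of 14, or 7 and 2 adjusted over the list alone (adjusted p = 0.0812). Oxidative stress and detoxification genes held 3 rises, with Keap1 at 1.17 ± 0.10 log2, and 2 falls of 15, also adjusted over the list alone (adjusted p = 0.915). Cell shape and disc eversion genes held 5 rises, with the matrix protease gene Mmp2 at 1.42 ± 0.14 log2, and 4 falls of 16, with the integrin gene if at -1.66 ± 0.09, also adjusted over the list alone (adjusted p = 0.812). The falls numbered 2 without 0 nM replicate 1, 0 nM replicate 3, 2000 nM replicate 2 or 2000 nM replicate 3. Cuticle and apical matrix genes held 4 rises, with pio at 0.91 ± 0.06 log2, and 3 falls of 14, or 4 and 4 adjusted over the list alone (adjusted p = 0.655), and 4 and 5 without 2000 nM replicate 2.

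Markers of other cell types went both ways at 2000 nM against 0 nM. Of 9 blood cell markers, Ppn rose by 3.19 ± 0.14 log2 while the collagen IV genes Col4a1 and vkg fell by 0.78 ± 0.09 and 0.93 ± 0.12, and no other passed, also adjusted over the list alone (adjusted p = 0.812). Adult muscle precursor markers held 3 rises and 5 falls of 13, with htl at -0.71 ± 0.10 log2, or 4 and 5 adjusted over the list alone (adjusted p = 0.365). Tracheal markers held 3 rises and 3 falls of 9, with Cht5 at 1.62 ± 0.10 log2, or 4 and 3 adjusted over the list alone (adjusted p = 0.812). Of 4 neuron and glia markers elav alone rose, by 0.93 ± 0.16 log2, also adjusted over the list alone (adjusted p = 0.651). Fat body markers held 1 rise and 2 falls of 9 (adjusted p = 0.578), and the markers of other imaginal discs 5 rises and 1 fall of 7 (adjusted p = 0.0812), both also adjusted over the list alone. The fat body markers held 1 fall and no rise without 0 nM replicate 1, 2000 nM replicate 2 or 2000 nM replicate 3, and 1 rise and 4 falls without 0 nM replicate 2. The salivary gland list had too few tested members for a list test.

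From 20 to 200 nM, 358 genes rose and 318 fell. Hr4 rose 67.3-fold, Eip78C 19.4-fold, ImpE1 17.6-fold, Cyp18a1 12.1-fold and tnc 10.8-fold, while br rose by 1.02 ± 0.13 log2 and Eip75B by 0.66 ± 0.11. Blimp-1 rose by 6.65 ± 0.44 log2, and by 7.32 without 20 nM replicate 1. The amino acid transporter genes mnd and path rose 5.44-fold and 5.28-fold. Eip74EF fell by 0.90 ± 0.08 log2, as did ftz-f1 by 3.58 ± 0.38 log2, hdc by 7.19-fold, fru by 5.60-fold and chinmo by 5.54-fold. Myc stood at 3079 ± 249 and 2862 ± 371 normalised counts and was not called.

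By list, 12 ecdysone response genes rose and 5 fell from 20 to 200 nM, also adjusted over the list alone (adjusted p = 6.56e-07, and adjusted p = 0.113 with an estimated correlation). Glycolysis genes held 8 falls and 1 rise (10 and 1 adjusted over the list alone, adjusted p = 5.1e-08, and adjusted p = 0.121 with an estimated correlation), with Pfk at -0.84 ± 0.09 log2 and Pgi at -0.64 ± 0.09. Insulin, TOR and FOXO genes held 4 rises and no fall (5 and 0 adjusted over the list alone, adjusted p = 0.000878, and adjusted p = 0.113 with an estimated correlation), with Pdk1 up 2.84-fold. Wing patterning and growth signalling genes held 10 rises and 1 fall (13 and 1 adjusted over the list alone, adjusted p = 4.23e-05, and adjusted p = 0.438 with an estimated correlation), with wg at 0.56 ± 0.08 log2 and the proneural gene sc at 0.73 ± 0.12. They held 6 rises and no fall without 20 nM replicate 2 or 20 nM replicate 3, and 7 and none without 200 nM replicate 3. G2/M and mitosis genes held 5 falls and no rise (7 and 0 adjusted over the list alone, adjusted p = 2.62e-06, and adjusted p = 0.438 with an estimated correlation), with tum at -0.42 ± 0.07 log2. The falls numbered 1 without 20 nM replicate 3 or 200 nM replicate 3, 2 without 20 nM replicate 1 or 200 nM replicate 2, and 3 without 200 nM replicate 1 or 20 nM replicate 2. DNA replication and G1/S genes held 1 rise and 1 fall, also adjusted over the list alone, and ribosome biogenesis genes neither, and both lists had adjusted p = 0.91. The replication rise was lost without 20 nM replicate 2, 20 nM replicate 3 or 200 nM replicate 3, and 1 ribosome biogenesis gene fell without 200 nM replicate 1.

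Apoptosis and wound stress genes held 3 rises from 20 to 200 nM, also adjusted over the list alone, with Dronc at 0.88 ± 0.08 log2. That list had adjusted p = 0.0116, range 0.00182 to 0.0524 over its alternatives, was lost without 20 nM replicate 1 (0.0524), and had adjusted p = 0.438 with an estimated correlation. Adult muscle precursor markers held 4 falls (4 falls and 1 rise adjusted over the list alone), with htl at -0.60 ± 0.10 log2 and stumps at -0.47 ± 0.09. The markers had adjusted p = 0.0157, range 0.00556 to 0.0583 over their alternatives, were lost without 20 nM replicate 1 (0.0583), and had adjusted p = 0.438 with an estimated correlation. Notch target genes held 2 falls, or 4 adjusted over the list alone, at adjusted p = 0.024, range 0.00419 to 0.103 over the alternatives. They were lost without 200 nM replicate 1 (0.103) and without 20 nM replicate 3 (0.0637), and had adjusted p = 0.441 with an estimated correlation. Their falls numbered 0 without either of these libraries, 20 nM replicate 2, 0 nM replicate 2 or 0 nM replicate 3, and 1 without 200 nM replicate 3 or any 2000 nM library.

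Between 2000 and 20 nM, 702 genes rose and 680 fell. Hr4 rose 169-fold, Eip78C by 4.91 ± 0.16 log2, Cyp18a1 28.6-fold, ImpE1 27.6-fold and the TGF-beta family gene daw 9.83-fold. Blimp-1 rose by 7.45 ± 0.44 log2, and by 8.12 without 20 nM replicate 1. Falls included ftz-f1 by 27.0-fold, a log2 fold change of -4.75 ± 0.38 and of -5.40 without 2000 nM replicate 3, hdc by 8.69-fold, DOR by 6.25-fold and Ugt35A1 by 5.75-fold. EcR fell by 0.87 ± 0.09 log2 and stg by 0.47 ± 0.10. G2/M and mitosis genes held 26 falls and no rise (29 and 1 adjusted over the list alone, adjusted p = 8.55e-11, and adjusted p = 0.229 with an estimated correlation), or 15 falls without 20 nM replicate 1 and 17 without 2000 nM replicate 3. DNA replication and G1/S genes held 8 falls and 1 rise (13 and 1 adjusted over the list alone, adjusted p = 4.87e-05, and adjusted p = 0.485 with an estimated correlation), with Mcm6 at -0.34 ± 0.08 log2, or 3 falls and 1 rise without 20 nM replicate 1 and 2 and 1 without 2000 nM replicate 3. Glycolysis genes held 9 falls and 1 rise (10 and 1 adjusted over the list alone, adjusted p = 1.85e-06, and adjusted p = 0.228 with an estimated correlation).

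Wing patterning and growth signalling genes held 18 rises and 2 falls between 2000 and 20 nM (19 and 2 adjusted over the list alone, adjusted p = 3.13e-07, and adjusted p = 0.229 with an estimated correlation), with wg at 0.87 ± 0.08 log2, or 13 rises and no fall without 2000 nM replicate 3. Ecdysone response genes held 12 rises and 5 falls, also adjusted over the list alone (adjusted p = 2.17e-06, and adjusted p = 0.123 with an estimated correlation). Apoptosis and wound stress genes held 9 rises and 1 fall (11 and 1 adjusted over the list alone, adjusted p = 9.55e-05, and adjusted p = 0.229 with an estimated correlation), with Dronc at 1.19 ± 0.08 log2, or 5 rises and no fall without 2000 nM replicate 3. Insulin, TOR and FOXO genes held 5 rises and 1 fall (6 and 1 adjusted over the list alone, adjusted p = 0.000765, and adjusted p = 0.123 with an estimated correlation). Heat shock genes held 5 rises and 1 fall (7 and 1 adjusted over the list alone, adjusted p = 0.00814, and adjusted p = 0.45 with an estimated correlation), with Hsp27 at 1.08 ± 0.15 log2, or 3 rises and 1 fall without 2000 nM replicate 3 or any 20 nM library. Ribosome biogenesis genes held 1 fall, RpI1, also adjusted over the list alone, at adjusted p = 0.0181, range 0.00157 to 0.0798 over the alternatives. They were lost without 2000 nM replicate 1 (0.0698) and replicate 3 (0.0798), and had adjusted p = 0.485 with an estimated correlation. Their falls numbered 2 without 0 nM replicate 1, 20 nM replicate 1, 200 nM replicate 2, 200 nM replicate 3, 2000 nM replicate 2 or 2000 nM replicate 3. Adult muscle precursor markers held 5 falls and 1 rise (6 and 1 adjusted over the list alone) at adjusted p = 0.0477, range 0.0167 to 0.157 over the alternatives, and had adjusted p = 0.485 with an estimated correlation. Their call ended without 20 nM replicate 1 (0.0947), 200 nM replicate 1 (0.0526), 0 nM replicate 2 (0.0505), 200 nM replicate 2 (0.0563) or 2000 nM replicate 2 (0.157), and under 5 of the other alternatives.

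Between 2000 and 200 nM, 14 genes rose and 3 fell, while 918 genes had an unadjusted p under 0.05 in the moderated test. Chance alone would give 423 on average. Genes that move together make that number vary, and its spread was not computed, so the excess was not tested. Hr4 rose 2.51-fold, from 4531 ± 88.0 to 11390 ± 848 normalised counts, at adjusted p = 0.0104, range 5.49e-06 to 0.0926 over its alternatives. The gene neo, which encodes a zona pellucida domain protein of the apical matrix, rose by 0.44 ± 0.06 log2 at adjusted p = 0.02, range 0.00453 to 0.0926. The Hr4 call ended without 2000 nM replicate 1 (0.0926) or 200 nM replicate 3 (0.0587), and that of neo without 2000 nM replicate 1 (0.0926), 200 nM replicate 2 (0.0797) or 200 nM replicate 3 (0.0902), and in a fit of only these 2 doses (0.0735). Values for genes that were not called were 0.63 ± 0.16 log2 for Eip78C, 0.37 ± 0.11 for Eip75B, -0.23 ± 0.09 for EcR and -1.17 ± 0.38 for ftz-f1. The count of 17 fell to 0 without 2000 nM replicate 1 or 200 nM replicate 3, to 2 without 200 nM replicate 1, to 4 without 200 nM replicate 2, to 6 without 2000 nM replicate 3, to 9 without 2000 nM replicate 2 and to 10 without 20 nM replicate 2. Without 2000 nM replicate 3 the balance turned, with 2 rises and 4 falls. The replicate block gave 46 genes, with 33 rises and 13 falls.

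Some lists moved by small amounts between 2000 and 200 nM, although Hr4 was the only member called over all genes. Without 0 nM replicate 2, 0 nM replicate 3 or 2000 nM replicate 3, 2 ecdysone response genes were called, and without 2000 nM replicate 1 or 200 nM replicate 3 none. DNA replication and G1/S genes lay lower with a median of -0.19 log2 (1 fall adjusted over the list alone, adjusted p = 3.28e-11), G2/M and mitosis genes with -0.15 (0 adjusted over the list alone, adjusted p = 3.87e-09) and ribosome biogenesis genes with -0.09 (0 adjusted over the list alone, adjusted p = 0.000296). Ecdysone response genes lay higher (9 rises and 2 falls adjusted over the list alone, adjusted p = 5.72e-05), as did wing patterning and growth signalling genes (0 adjusted over the list alone, adjusted p = 5.72e-05) and apoptosis and wound stress genes (2 rises adjusted over the list alone, adjusted p = 0.000556). Each of these lists, and the heat shock list, had adjusted p = 0.262 with an estimated correlation. Heat shock genes lay higher (0 adjusted over the list alone) at adjusted p = 0.00849, range 0.00117 to 0.0544 over the alternatives, and were lost without 200 nM replicate 1 (0.0544).

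The F test for a difference at any dose called 2000 genes. The authors' likelihood ratio test over the doses has an adjusted p under 0.05 for 2435 of 9374 genes. Of the genes tested in both, 1892 were called by both, all with the same sign of the change at 2000 nM, 108 by limma alone and 512 by the authors alone. Across the 8455 tested genes the deposited and the computed log2 fold changes of 2000 against 0 nM correlated at 0.991, genes not being independent replicates.

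A gene was dose-reversing when it moved one way from 0 to 20 nM and back from 20 to 2000 nM, and 4 genes rose then fell and 4 fell then rose. With the replicate block these numbered 8 and 4. Eip74EF went from 539 ± 13.1 normalised counts at 0 nM to 2277 ± 193 at 20 nM, 1222 ± 69.4 at 200 nM and 1517 ± 127 at 2000 nM, so that it fell by 0.59 ± 0.08 log2 after its rise. The gene pigs rose by 0.90 ± 0.17 log2 and fell by 0.86 ± 0.17, and the bHLH gene net, a regulator of wing vein formation, rose by 0.72 ± 0.10 and fell by 0.62 ± 0.10. Fatp1 rose by 0.52 ± 0.11 log2 (adjusted p = 0.00791, range 0.00298 to 0.0505) and fell by 0.44 ± 0.11 (adjusted p = 0.011, range 0.00262 to 0.0573). Its rise was lost without 20 nM replicate 3 (0.0505), and its fall without 2000 nM replicate 1 (0.0544) or 20 nM replicate 3 (0.0573). The gene sca fell by 0.35 ± 0.08 log2 (adjusted p = 0.0144, range 0.00474 to 0.0877) and rose by 0.46 ± 0.08, and its fall was lost without 20 nM replicate 2 (0.0877) or 0 nM replicate 3 (0.0793). Chosen after their values were seen, the others that fell then rose were ich by 3.09 ± 0.35 and 1.59 ± 0.35 log2, CG32365 by 1.01 ± 0.14 and 0.79 ± 0.14, and CG43861 by 1.37 ± 0.20 and 1.10 ± 0.20.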

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

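The fits with limma-voom, with thinned libraries and from the authors' likelihood ratio test were chosen after seeing the data, as were the list tests with TMM scaling and with a filter at 50 and the named-gene fits of only the 2 doses compared. The planned edgeR and DESeq2 fits were not run, although whole reads could be recovered, and limma-voom is the only count-based fit made of those reads. Of 435 called results for named genes, 363 kept their call under each of the 22 settings that tested them, and none changed direction. The filter at 50 left some named genes untested, and such results do not count as lost. The lost calls numbered 0 with a pseudocount of 5, 1 each with a pseudocount of 0.5, TMM scaling or the replicate block, 2 with a filter at 50, 7 each with quantile normalisation or limma-voom, 10 with no filter, 19 with only the 2 doses compared, 21 with thinned libraries, and 10 to 45 with 1 library left out. The total counts of changed genes stayed within 1.5 times the reported ones under the alternatives run, with the following exceptions. A minimum change of 2-fold, which removes smaller changes by construction, left 127 genes for 20 nM against 0 nM, 491 for 200 nM against 0 nM, 714 for 2000 nM against 0 nM, 182 for 200 nM against 20 nM, 4 for 2000 nM against 200 nM, 302 for 2000 nM against 20 nM and 2 dose-reversing genes. The count of 17 for 2000 nM against 200 nM became 46 with the replicate block and 8 with thinned libraries, and 0 to 18 with 1 library left out, and the cause was not tested. The block also gave 12 dose-reversing genes, from 8, of which 8 rose then fell, from 4. It lowered the median SE from 0.109 to 0.0927. By direction, the 130 falls at 20 nM against 0 nM became 79 without 20 nM replicate 2. The labels do not say whether the replicate numbers pair the libraries, and the values leave it open: of 18 pairs with the same number, 7 correlated above 0.1, from -0.37 to 0.40, and 6 of 12 libraries correlated best with their own number. With 1 library left out, the number of called members moved by over 1.5 times, in total or in a direction of at least 3, in 49 of 126 combinations of a list and a comparison, those in the text being given beside their counts. In 17 more only a direction of 1 or 2 did, and adjusted over the list alone the total did in 53. Of 126 list tests 47 were called, 45 to 53 under the other settings, and 2 with the estimated correlation, both for ecdysone response genes. The median, mean and test of a list differed in sign in 20 of the 126 tests, none of them called. No scaling moved the median log2 fold change of all genes by over 0.1. Depth limits the precision at low counts, since the shallowest 20 nM library has 1836 genes at 0 and the deepest 2000 nM library 583.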

Other observations

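The 6 gene families, the equal-read and phm ratio tests, the levelling tests other than the percentage of genes further from 0 nM, and the simulated common shares were chosen after results were seen, while the other tests were written before theirs. At 2000 nM against 0 nM, 31.0% of all 8455 tested genes changed, 1306 rising and 1312 falling, and the family counts stand beside that share. In that comparison 10 of 19 vacuolar ATPase subunit genes fell and 1 rose, or 11 and 1 under quantile normalisation. These genes encode the proton pump of endosomes and lysosomes. Vha68-2 fell by 0.71 ± 0.05 log2 (SE), VhaSFD by 0.61 ± 0.07 and Vha100-2 by 0.59 ± 0.06, while Vha36-3 rose by 2.31 ± 0.64 (adjusted p = 0.0137), a call lost without 2000 nM replicate 3 (0.0794). The family had adjusted p = 0.000618 over the 6 families, and adjusted p = 0.0587 with an estimated correlation (0.112 with TMM scaling and 0.347 with quantile normalisation). At 200 nM 10 of its genes fell and none rose, with adjusted p = 7.29e-05, and adjusted p = 0.0225 with an estimated correlation, which was 0.047 with TMM scaling and 0.198 with quantile normalisation. Of 22 nucleoporin genes, 12 fell and none rose at 2000 nM, or 15 under quantile normalisation, with Nup133 at -0.59 ± 0.12 log2 and Nup205 at -0.54 ± 0.09 (adjusted p = 9.99e-05, and adjusted p = 0.362 with an estimated correlation). The falls numbered 6 without 0 nM replicate 3 and 5 without 2000 nM replicate 3. Of 72 mitochondrial ribosomal protein genes 20 fell and none rose, under quantile normalisation too, with mRpS30 at -0.76 ± 0.07 log2 (adjusted p = 0.000618, and adjusted p = 0.561 with an estimated correlation). These falls numbered 8 without 0 nM replicate 3 or 2000 nM replicate 1, and 11 without 2000 nM replicate 3.

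Of 86 cytoplasmic ribosomal protein genes, only RpS19b was called at 2000 nM, at 2.09 ± 0.33 log2 under the deposited scaling, and the family median was -0.03 with the same sign under each scaling (adjusted p = 0.491), while 2 rose without 0 nM replicate 2. Of 34 proteasome subunit genes 9 rose and none fell, or 3 and none under quantile normalisation, with Rpn10 at 0.30 ± 0.08 log2 (adjusted p = 0.00105, and adjusted p = 0.561 with an estimated correlation). The rises numbered 2 without 0 nM replicate 1 or 2000 nM replicate 2, 3 without 0 nM replicate 3, 4 without 20 nM replicate 2, and 5 without 20 nM replicate 3 or 2000 nM replicate 3. Of 182 transposable element entries 17 rose and 2 fell, but 10 rose and 7 fell under quantile normalisation, where the median turned from 0.06 to -0.21 (adjusted p = 0.412), and 7, 9 and 10 rose without 2000 nM replicate 3, 0 nM replicate 3 and 2000 nM replicate 1. The 17 rises and the 2 falls were each a smaller share than over all tested genes.

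Genes that changed at least 2-fold at 2000 nM differed in how much of that log2 change they had reached at 20 nM. Across the 456 such genes with a mean of at least 50 normalised counts over all libraries the median share was 38.1%, with quartiles of 28.7% and 48.3%, while it was 139% for Eip74EF, 98.3% for vri, 84.4% for Eip75B, 25.5% for ftz-f1 and 16.6% for Hr4. Measurement error around 1 common share was argued against, as 30.3% of the genes lay outside the 95% interval around it, against a bound of 15% and at most 27.9% in 100 simulated sets, a narrow margin. So was compression of low values at 0 nM, with 32.2% among the 345 genes with a 0 nM mean of at least 100 and at most 29.9% in the simulated sets. Falling genes with low values at the higher doses, such as ftz-f1, stay in that set, so compression there was not tested. The 20 nM replicate 1 library was argued against too, with 31.7% without it and at most 27.8%. The 16 ecdysone response genes had a median share of 42.5% against 37.9% for the others, a difference of 0.0459 as a fraction (one-sided permutation p = 0.142, 100000 permutations), so that whether they reach more of their change at 20 nM stays open, and whether genes differ in the hormone level at which they respond was not tested.

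Few genes changed between 200 and 2000 nM, where the 200 nM libraries were the shallowest on average. At equal reads 590 genes changed between 20 and 200 nM and 8 between 200 and 2000 nM, which argues against fewer reads as the only cause. Thinning took the second count from 17 to 8, so reads still bear on it. Of the 381 genes changed at 20 nM, 79.8% lay further from 0 nM at 2000 than at 200 nM, above the 65% bound written beforehand, and 75.3% to 82.4% did with 1 of the 6 libraries left out. Other splits of these libraries, which keep part of a dose difference, gave up to 77.4%, and up to 56.4% once each gene's dose means were removed. With 1 mean per library over the 381 genes, signed by their direction at 20 nM, the 2000 nM libraries lay 0.187 log2 further than the 200 nM libraries (95% interval 0.141 to 0.233). A complete levelling off of these genes as a whole by 200 nM is therefore argued against, as it is for the 251 rising genes alone (0.228, 0.196 to 0.26), while for the 130 falling genes it stays open (0.107, -0.066 to 0.28). For the ecdysone response genes it is argued against too. Of 22, 11 differed between 200 and 2000 nM adjusted over the list alone, 9 rises and 2 falls. The number was 7 without 200 nM replicate 1, 2000 nM replicate 1 or 2000 nM replicate 2. The other splits gave at most 1, but their spread holds the dose difference, which lowers their count by construction. The log2 fold change of Hr4, the only list member called over all genes here, stayed between 1.27 and 1.37 with each 200 or 2000 nM library left out. Leaving out a 0 or 20 nM library cannot move it. Its call over all genes was lost without 2000 nM replicate 1 or 200 nM replicate 3.

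The phm gene rose beside its neighbour Cyp18a1, at a fraction of its level. As a percentage of Cyp18a1 it stood at 80.4 ± 58.3 at 0 nM, 35.3 ± 5.30 at 20 nM, 13.1 ± 0.993 at 200 nM and 5.76 ± 1.02 at 2000 nM (SD, n = 3). The 0 nM libraries held only 7, 4 and 14 reads of phm and 9, 17 and 10 of Cyp18a1. Their percentages ran from 23.5 to 140, so the 0 nM value is too imprecise to read as the start of a trend. The ratio at 20 nM was 6.14 times that at 2000 nM, with no overlap between libraries, which argues against Cyp18a1 reads counted for phm at a constant rate as the cause. A rise of phm itself in these discs stays open as a hypothesis, and a rate of miscounting that changes with dose was not tested.

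Each pairwise comparison has 10 splits of its 6 libraries, too few for a share under 0.05. The real split alone reached its own count in each, 1 of 10. The real counts were 381 for 20 nM against 0 nM, 1721 for 200 nM against 0 nM, 2618 for 2000 nM against 0 nM, 676 for 200 nM against 20 nM, 17 for 2000 nM against 200 nM and 1382 for 2000 nM against 20 nM. The highest other splits gave 0, 0, 1, 0, 12 and 0 in that order. For a difference at any dose, 1 of 100 splits, the real one, reached 2000 genes. The highest other gave 1695, so chance is argued against, but 100 splits cannot exclude it. For the 8 dose-reversing genes, 4 of 100 splits gave as many, the real one included, and the others gave 83, 94 and 1319, so the count of splits leaves chance open. In those 3 a dose's libraries had stayed together as the middle group, which points to a structure of the samples. With the doses relabelled so that 0 nM or 2000 nM was the middle one, 373 and 1322 genes met the rule. Such genes differed from that middle dose in the same direction at both other doses. A steady response to dose gives such genes, so neither count measures chance.

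The comparisons with 0 nM share those 3 libraries, too few to be divided between them. Of the 251 genes that rose at 20 nM, 249 also rose at 200 nM, where independent lists would share 24.9, and 247 at 2000 nM, where they would share 38.8. Of the 130 that fell, 128 also fell at 200 nM, where independent lists would share 13.6, and 126 at 2000 nM, where they would share 20.2. In 100 simulated sets with unchanged groups, no gene was shared. Unchanged groups yield few calls, so these sets cannot show how far the shared libraries raise the overlap of real changes. The comparisons behind dose reversal share the 20 nM libraries. The 4 genes in each direction stand beside 20.2 and 10.8 for independent lists. The simulated sets gave at most 1 and 0, with the same limit.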
